A study of Homo sapiens with 6 samples.

How the data were processed

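The samples were 6 preparations of PC9, an established human lung adenocarcinoma cell line, per the labels. The 3 HCI-2509 samples had received medium with 2 µM of the compound 24 h after plating and were harvested 48 h later. The 3 untreated samples were PC9 cells without the compound. What vehicle they received, if any, is not given in the sources used here. RNA was isolated on an automated Maxwell system, and 100 ng was amplified and labelled as biotinylated cDNA for whole-transcript arrays, per the labels' protocols. The labels number the replicates of each group but do not say that they came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

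The deposited values are log2 signals, 1 per probe set and array, as their range of 1.44 to 14.34 shows. They were made with the Transcriptome Analysis Console, per the submitters' processing notes. The version, the method of summarization and normalization and the genome build are not given in the sources used here, and for that reason no coordinates are printed. Array medians differed by at most 0.09, under the limit of 0.1 set for further normalization, so the deposited values were used without rescaling. That limit was read over all probe sets. Over the genes tested the medians ran from 5.27 to 5.40, a wider range, with HCI-2509 replicate 1 highest, and rescaled values are among the alternatives. Log2 changes of weakly expressed genes are understated where background makes up most of their signal.

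Each array holds 53617 probe sets. In the platform annotation used here 16098 of them name exactly 1 gene. The other 37519 are called probe sets without a gene name below. Any that name several genes are among them and were not counted apart. All 16098 were matched to current gene records through their Entrez number, and 0 symbols changed. For the 779 genes with more than 1 probe set the one with the highest mean over the 6 arrays was taken, which left 14884 genes. No gene was left out for low signal.

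Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only factor), with Benjamini-Hochberg adjustment over the 14884 genes and a threshold of 0.05. No test was run on fewer than 3 arrays per group except where an array was left out on purpose. A group of genes was tested with limma's camera (two-sided, preset inter-gene correlation of 0.01), adjusted over the 27 lists with at least 5 measured genes. With that preset its degrees of freedom come from the number of genes, so its p-values do not measure the spread between samples. The lists, the rule for naming genes, the tests and the alternatives were fixed before the data were examined, except where stated. Of 35 lists, drawn from textbook knowledge, 27 were tested and 4 (CDK inhibitors, antigen presentation, fibroblast markers, leukocyte markers) had fewer than 5 measured genes and are given as values. Lists of replication-dependent histones, tubulins, integrins and mitochondrially encoded genes had 0 measured members and are not analysed here. Together the lists hold 775 distinct genes, of which 406 were measured.

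The genes named were KDM1A and 1 integrin gene that is not analysed here; the 12 largest rises and 12 largest falls among genes that passed, whose treated arrays all lay on one side of the untreated ones and whose mean in the higher group was above the median of all genes (5.34), leaving out uncharacterised loci and small RNAs; and for each list up to 4 passing members with the largest change or, with 0 passing, the 1 with the largest change. This gave 73 genes, 59 of them passing. Further members of a list that are named (MKI67, FOXM1, MCM6, PHGDH, SHMT2, ATF3, ATF4, DDIT3, VEGFA, VIM, ESRP1, DUSP5, EGFR, SDF2L1 and GDF15) were chosen after their values were seen.

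The same steps were tested on simulated data of 14884 genes with the real arrays' means and spread, in which 100 genes were changed by 1 and 100 by 2 on the log2 scale and the mitosis list was shifted by -0.6. They recovered 82% of the genes changed by 1 and 100% of those changed by 2, and 5.53% of 199 calls were unchanged genes. The shifted list was the 1 list called. Genes were simulated as independent and no array was made to lie apart. The simulation therefore does not show how the tests behave with correlated genes or a deviating array.

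Alternatives were quantile normalization, median centring, cyclic loess normalization, a filter on dim genes, eBayes with an intensity trend and robust estimation, a linear model without variance moderation, array weights, the mean of a gene's probe sets, genes with a single probe set, the replicate number as a block, leaving out each array in turn, treat against a 1.2-fold change, an unadjusted p with a 2-fold change, and for lists an estimated inter-gene correlation and the rotation test fry. Testing all probe sets together was added after the data were seen. Probe sets without a gene name were tested separately and take no part in the counts of genes. The precision of each value is limited by the number of arrays, 3 per group, and the median standard error of a log2 change was 0.17.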

Results

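Whole-transcript microarrays measured total RNA from PC9 cells, an EGFR-mutant human lung adenocarcinoma line. The comparison asks how gene expression differs after 48 h in medium with 2 µM HCI-2509, an inhibitor of the histone demethylase LSD1 (encoded by KDM1A). There were 3 untreated arrays and 3 HCI-2509 arrays, and their number limits the precision of every value. Median log2 signal lay between 4.41 and 4.50 on the 6 arrays. HCI-2509 replicate 1 stood apart: its correlation with the other arrays, across all probe sets, was 0.943 to 0.959, whereas the other 5 arrays correlated with one another at 0.967 to 0.981. The log2 signal that its brightest 10% of probe sets exceeded was 7.73, against 8.09 to 8.13 on the others. Changes below are log2 differences, HCI-2509 minus untreated, with the standard error of the limma fit (n = 3 arrays per group).

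HEPHL1, a copper-dependent ferroxidase, was among the largest rises with HCI-2509, at 3.88 ± 0.16, or 14.7-fold, and FN1, the matrix protein fibronectin, rose by 3.18 ± 0.13, or 9.06-fold (adjusted p = 8.01e-05 for both). Genes of mitosis and targets of the transcription factor ATF4 were lower as lists, and hypoxia and mesenchymal genes were higher. None of these 4 calls held with an estimated correlation between genes (adjusted p = 0.207 for mitosis, ATF4 targets and mesenchymal genes, and 0.315 for hypoxia genes). For ATF4 targets and mesenchymal genes that estimate was -0.0046 and -0.013, below the preset 0.01. Correlation between genes therefore does not account for the loss of those calls. With an estimated correlation camera also takes its degrees of freedom from the arrays, and with the preset from the genes. That difference applies to every list, and its share in the losses was not tested. PLK1, a kinase of mitotic entry and spindle assembly, fell by 1.62 ± 0.14 on the log2 scale (adjusted p = 0.00147), and PSAT1, an aminotransferase of serine synthesis, fell by 2.15 ± 0.23 (adjusted p = 0.00374). KDM1A itself, the target of the compound, went from 12.31 ± 0.023 (SD, n = 3) in untreated cells to 11.75 ± 0.056 in treated cells, a change of -0.56 ± 0.12 (adjusted p = 0.0386). That call was lost on leaving out any 1 array other than HCI-2509 replicate 1 (adjusted p between 0.0946 and 0.152) and after cyclic loess normalization (adjusted p = 0.0714).

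In all, 766 of 14884 genes tested (5.15%) passed an adjusted p of 0.05, 348 higher and 418 lower with HCI-2509. Of these, 343 changed at least 2-fold, 153 of them higher and 190 lower. The 3 treated arrays lay entirely on one side of the 3 untreated arrays for each of the 766 genes, a separation seen for 28.9% of all genes tested and for 10% by chance. The count depended on the arrays used. Without HCI-2509 replicate 1 it was 1217 genes (622 higher, 595 lower), of which 726 were among the 766. Without HCI-2509 replicate 2 or 3 it was 419 or 392, and without untreated replicate 1, 2 or 3 it was 194, 184 or 225.

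**Figure D1:**
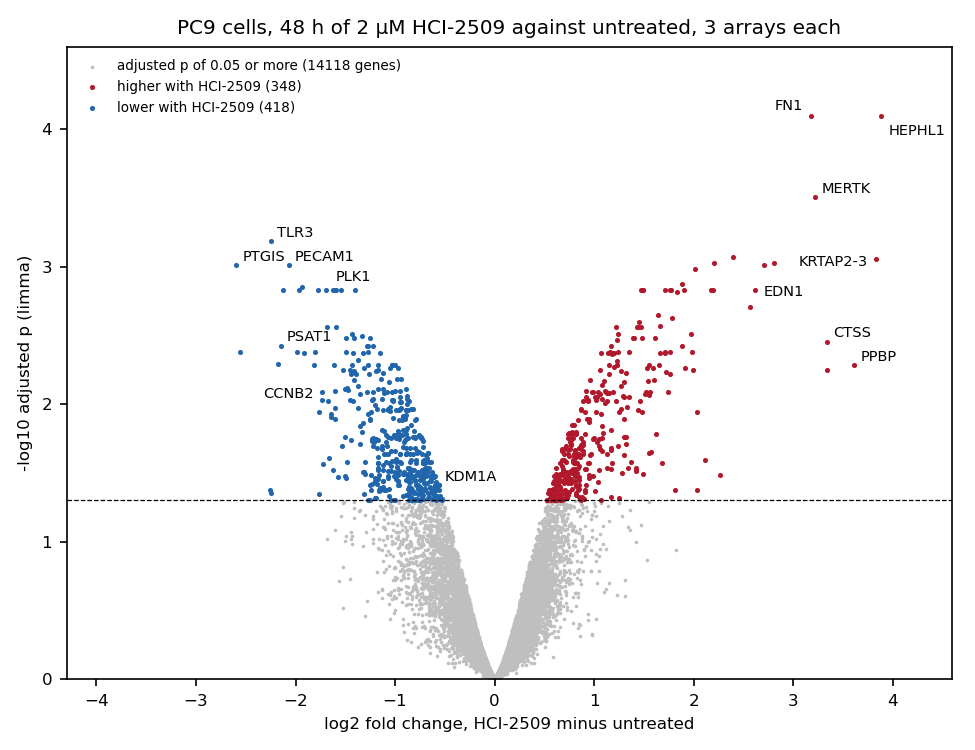
Log2 fold change of each of the 14884 genes (HCI-2509 minus untreated, horizontal) against the negative log10 of its limma adjusted p (vertical), with the dashed line at an adjusted p of 0.05. Red points are the 348 genes that were higher and blue points the 418 that were lower with HCI-2509, and grey points did not pass; HEPHL1 and FN1 have the smallest adjusted p.

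The 12 largest rises ran from 2.40 to 3.88. Beside HEPHL1 stood KRTAP2-3, a hair keratin-associated protein (3.84 ± 0.25), PPBP, a platelet chemokine (3.61 ± 0.44), and CTSS, the lysosomal protease cathepsin S (3.34 ± 0.35). SPRR1B and SPRR1A, small proline-rich proteins of the cornified envelope of squamous epithelium, rose by 3.34 ± 0.42 and 2.71 ± 0.19. The SPRR and KRTAP genes belong to families of similar sequence, so the assignment of their signal to a single member is uncertain. MERTK, a receptor tyrosine kinase of the same family as AXL, rose by 3.22 ± 0.17. DENND2C, a DENN domain protein (2.81 ± 0.19), EDN1, the peptide endothelin (2.62 ± 0.22), VTCN1, an inhibitory immune ligand (2.57 ± 0.23), and VGLL3, a cofactor of TEAD transcription factors (2.40 ± 0.15), completed the group with FN1. PPBP was 6.05 on HCI-2509 replicate 1 against 7.82 and 7.73 on the other treated arrays, and its change without that array was 4.19, above HEPHL1 (3.80) and KRTAP2-3 (3.84), so the order of these 3 depends on the array. The untreated levels of PPBP, KRTAP2-3 and CTSS, 3.59, 3.98 and 4.14, were below the median signal of every array, and their changes may be understated.

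Among the 12 largest falls were PTGIS, the prostacyclin synthase, at -2.60 ± 0.18, a 6.05-fold lower signal, and PRTFDC1, a homologue of a purine salvage enzyme, at -2.56 ± 0.29 (-2.41 and -2.67 without HCI-2509 replicate 1). GPX8, a peroxidase of the endoplasmic reticulum, changed by -2.25 ± 0.49 (adjusted p = 0.0417). Its level was 5.52 on HCI-2509 replicate 1 against 7.62 and 7.44 on the other treated arrays, and the change without that array was -1.58. TLR3, a receptor for double-stranded RNA, fell by 2.25 ± 0.13, and IL1RAPL2, a member of the interleukin-1 receptor family, fell by 2.18 ± 0.26. PSAT1 was next, followed by TRIM31, a ubiquitin ligase, at -2.13 ± 0.19 (another of its probe sets gave -2.39). PECAM1, an adhesion molecule of endothelial cells and platelets, fell by 2.07 ± 0.15. SPATA17, named for its expression in spermatogenesis, and CFAP263, a protein of cilia, changed by -1.99 ± 0.22 and -1.96 ± 0.17. ULBP1, a ligand of the natural killer cell receptor NKG2D, fell by 1.93 ± 0.15, and EREG, the EGFR ligand epiregulin, fell by 1.91 ± 0.22. The treated levels of TLR3 and PRTFDC1, 3.54 and 4.07, were below the median signal of every array, and their falls may be understated.

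Of 27 gene lists tested as groups, 6 passed camera at an adjusted p of 0.05 with the preset correlation of 0.01, 3 of them higher and 3 lower, and 0 passed with an estimated correlation. The mitosis list had the lowest p. Of its 30 measured members 15 fell and 0 rose (24 and 0 adjusted over the list alone), and all 30 changes were below 0, with a median of -0.67 (camera adjusted p = 9.15e-18; adjusted p = 0.207 with an estimated correlation). Without HCI-2509 replicate 1 the median was -0.56 and 18 members fell. CCNB2, a mitotic cyclin, fell by 1.73 ± 0.24 and KIF14, a kinesin of cytokinesis, by 1.67 ± 0.24. HMMR, a spindle-associated protein, fell by 1.61 ± 0.24, close to PLK1. The proliferation marker MKI67 was -0.29 and the transcription factor FOXM1 -0.01, and neither passed.

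The DNA replication list did not pass (camera adjusted p = 0.862). Of its 26 measured members 1 rose and 0 fell, with a median of 0.07 (2 rose and 1 fell adjusted over the list alone, and 3 rose and 0 fell, with a median of 0.04, without HCI-2509 replicate 1). The member that rose was CCNE2, a cyclin of the G1/S transition, at 1.32 ± 0.22 (adjusted p = 0.0172). MCM6, a subunit of the replicative helicase, was -0.63 (adjusted p = 0.0613).

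ATF4 targets, genes of the amino acid response, were lower as a list (camera adjusted p = 0.00554; adjusted p = 0.207 with an estimated correlation). Of 16 measured members 6 fell and 1 rose (7 and 2 adjusted over the list alone; 7 and 2 without HCI-2509 replicate 1), with a median of -0.31, or -0.34 without that array. Those that fell are enzymes of amino acid or one-carbon metabolism: PSAT1, PSPH and PHGDH of serine synthesis (-2.15, -1.37 and -0.95), CTH of cysteine synthesis (-1.44), ASNS of asparagine synthesis (-1.18) and SHMT2 of glycine synthesis (-0.89). ATF3, a stress-induced transcription factor, rose by 0.74 (adjusted p = 0.0335). ATF4 itself was -0.04 and DDIT3 -0.50, and neither passed.

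Hypoxia and glycolysis genes were higher as a list (camera adjusted p = 7.96e-06; adjusted p = 0.315 with an estimated correlation). Of 15 measured members 5 rose and 0 fell (9 and 0 adjusted over the list alone; 7 and 0 without HCI-2509 replicate 1), with a median of 0.45, or 0.48 without that array. ANKRD37, a target of hypoxia-inducible factor, rose by 2.17 ± 0.17, NDRG1, a hypoxia-induced cytoplasmic protein, by 1.33 ± 0.20, KDM3A, a histone demethylase, by 1.23 ± 0.15, and BNIP3, a mitophagy receptor, by 1.02 ± 0.15. VEGFA, the angiogenic growth factor, was 0.16 and did not pass.

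Mesenchymal markers were higher as a list, a call lost with an estimated correlation. Of 15 measured mesenchymal members 4 rose and 0 fell (7 and 0 adjusted over the list alone; 5 and 0 without HCI-2509 replicate 1), with a median of 0.42, or 0.39 without that array (camera adjusted p = 3.85e-04; adjusted p = 0.207 with an estimated correlation). FN1 was joined by AXL, a receptor tyrosine kinase (1.27 ± 0.16), THBS1, the matrix protein thrombospondin (1.11 ± 0.15), and SNAI2, a repressor of epithelial genes (1.06 ± 0.13). VIM, the intermediate filament vimentin, was 1.37 with an adjusted p of 0.059. Epithelial markers passed toward higher values (camera adjusted p = 0.0369), but not with an estimated correlation (adjusted p = 0.332), with array weights (0.0655), without HCI-2509 replicate 1 (0.109) or without untreated replicate 1 (0.0658). Of 20 measured epithelial members 4 rose and 1 fell, as they did adjusted over the list alone, and their median of 0.30 became 0.12 without HCI-2509 replicate 1. DSP, the desmosomal protein desmoplakin, rose by 1.45 ± 0.14, ST14, the membrane protease matriptase, by 1.04 ± 0.22 (adjusted p = 0.0647 after quantile normalization), OVOL1, a transcription factor of epithelial differentiation, by 0.80 ± 0.13 (another of its probe sets gave 0.35, and the mean of its probe sets did not pass, with adjusted p = 0.0676), and CLDN4, a tight junction claudin, by 0.75 ± 0.16. ESRP1, an epithelial splicing regulator, changed by -0.72 (adjusted p = 0.0265).

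Ribosomal protein genes passed toward lower values (camera adjusted p = 0.00672; adjusted p = 0.522 with an estimated correlation), although 0 of 26 measured members passed singly in limma, also adjusted over the list alone (1 had an unadjusted p under 0.05). The median was -0.24 and 24 of 26 values were below 0. Without HCI-2509 replicate 1 the median was -0.09 and the list did not pass (camera adjusted p = 0.0926), and it did not pass after cyclic loess normalization (0.0640). RPS23, a protein of the small subunit, was -0.69 ± 0.32, with 7.31 on HCI-2509 replicate 1 against 8.56 and 8.57 on the other treated arrays, and its change without that array was -0.27.

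**Figure D2:**
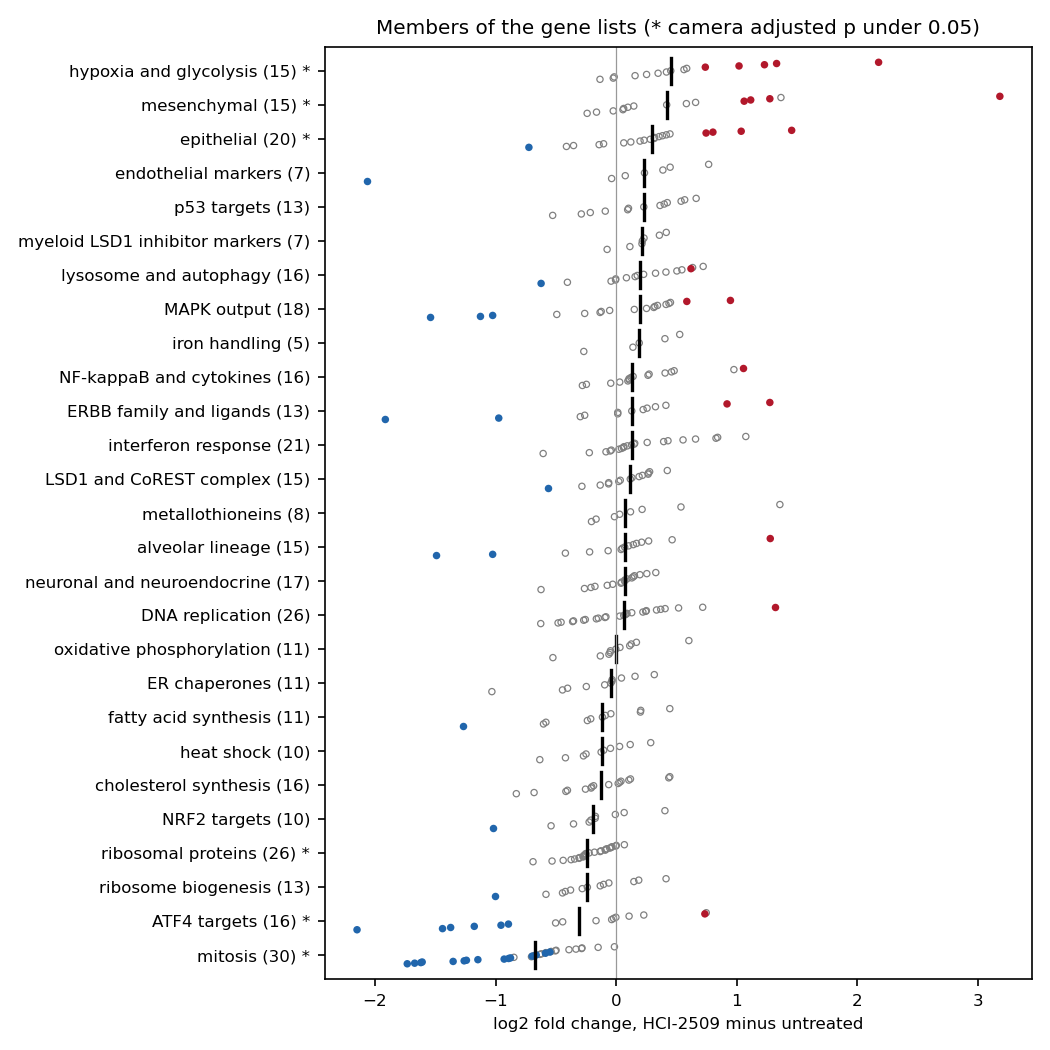
Log2 fold change (HCI-2509 minus untreated, horizontal) of each measured member of the 27 gene lists tested, 1 list per line with its number of measured members. Red and blue points passed an adjusted p of 0.05 as higher or lower, open points did not, black bars are list medians and an asterisk marks camera adjusted p under 0.05; all 30 mitosis members lie below 0.

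Lists of growth factor signalling held members that moved in opposite directions. Of 18 measured genes of MAPK output 2 rose and 3 fell (3 and 3 adjusted over the list alone or without HCI-2509 replicate 1), and the list did not pass camera (adjusted p = 0.994; median 0.20, or 0.06 without that array, and mean -0.03). ETV1 and ETV5, ETS transcription factors induced by ERK signalling, fell by 1.54 ± 0.13 and 1.02 ± 0.15, and DUSP6, an ERK phosphatase, by 1.12 ± 0.24. EPHA4, an ephrin receptor, rose by 0.95 ± 0.15, and DUSP5, another ERK phosphatase, by 0.59. Of 13 measured genes of the ERBB family and its ligands, with related receptors, 2 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.669). EGF, a ligand of EGFR, changed by -0.97 ± 0.21 beside EREG, and FGFR1, a fibroblast growth factor receptor, by 0.92 ± 0.18 beside AXL. EGFR was 0.41 (adjusted p = 0.226). Among 15 measured genes of the alveolar lineage 1 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.862, direction lower, with a median of 0.07, or -0.0011 without HCI-2509 replicate 1, and a mean of -0.03). FOXA1, a transcription factor of lung epithelium, fell by 1.49 ± 0.17 beside ETV5, and LAMP3, a lysosomal membrane protein of type II pneumocytes, rose by 1.28 ± 0.26. Without HCI-2509 replicate 1 the camera adjusted p of these 3 lists was 0.935, 0.510 and 0.536.

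**Figure D3:**
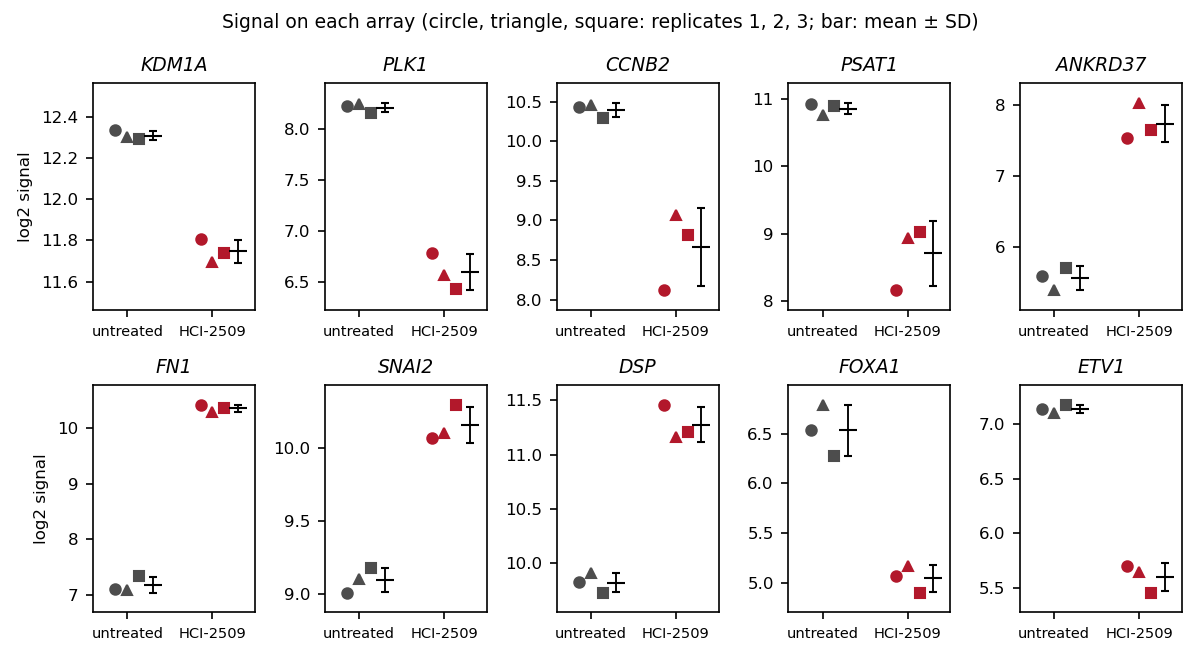
Log2 signal of 10 genes on each of the 6 arrays (grey untreated, red HCI-2509; circles, triangles and squares are replicates 1, 2 and 3), with horizontal bars at each group's mean and whiskers of 1 SD (n = 3). For CCNB2 and PSAT1 the lowest treated value is that of HCI-2509 replicate 1, and each vertical axis has its own range.

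Interferon and cytokine genes gave few calls. Of 21 measured interferon response genes 0 passed in limma, also adjusted over the list alone (4 higher and 1 lower at an unadjusted p under 0.05), while 4 rose without HCI-2509 replicate 1 (camera adjusted p = 0.142, and 0.0604 without that array). IFIH1, a sensor of double-stranded RNA, was 1.07 ± 0.25 (adjusted p = 0.0527), and without HCI-2509 replicate 1 it passed (adjusted p = 0.00415). Of 4 measured antigen presentation genes, given as values only, B2M, the light chain of class I molecules, rose by 0.90 ± 0.21 (adjusted p = 0.0492; 0.0644 after median centring). Of 16 measured genes of NF-kappaB and cytokines 1 rose, also adjusted over the list alone (camera adjusted p = 0.104): IL11, a cytokine of the interleukin-6 family, by 1.05 ± 0.18. Without HCI-2509 replicate 1, 2 members rose. The 7 measured myeloid genes known to respond to LSD1 inhibitors (camera adjusted p = 0.215) and the 17 neuronal and neuroendocrine genes (0.994) had 0 members that passed in limma, also adjusted over each list alone or at an unadjusted p under 0.05. Their largest changes were 0.42 ± 0.39 for LYZ, the enzyme lysozyme, and -0.62 ± 0.28 for REST, a repressor of neuronal genes. Both depended on HCI-2509 replicate 1: without it LYZ was 0.91 and passed (adjusted p = 0.0386), the 1 myeloid gene to do so, and REST was -0.28.

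The lists of NRF2 targets, fatty acid synthesis, ribosome biogenesis, lysosome and autophagy, and LSD1 with CoREST did not pass, though single members did. Of 10 measured NRF2 targets GSR, the glutathione reductase, fell by 1.02 ± 0.15 (camera adjusted p = 0.101, and 0.0406 without HCI-2509 replicate 1, where 2 members fell). Of 11 measured fatty acid synthesis genes ACACA, the carboxylase of the committed step, fell by 1.27 ± 0.14 (camera adjusted p = 0.142, and 0.0257 without HCI-2509 replicate 1), and 3 fell adjusted over the list alone. Of 13 measured ribosome biogenesis genes WDR12, a factor of large subunit assembly, was 2.01-fold lower (adjusted p = 0.0313; camera adjusted p = 0.0505, and 0.0354 without HCI-2509 replicate 1). Of 16 lysosome and autophagy genes CTSB, the protease cathepsin B, changed by 0.62 ± 0.12 and ATG16L1, an autophagy conjugation factor, by -0.62 ± 0.13 (camera adjusted p = 0.104), with 4 higher and 1 lower adjusted over the list alone and 2 higher and 1 lower without HCI-2509 replicate 1. The call of ATG16L1 was lost after quantile normalization (adjusted p = 0.0813) and after cyclic loess normalization (adjusted p = 0.0510). In the 15 measured genes of LSD1 and its CoREST complex, KDM1A alone passed, also adjusted over the list alone (camera adjusted p = 0.839).

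Lists with 0 members passing in limma were those of 13 p53 targets (camera adjusted p = 0.280; BBC3, an apoptosis inducer, 0.66 ± 0.30), 11 endoplasmic reticulum chaperones and regulators (0.288; XBP1, a stress transcription factor, -1.03 ± 0.25 with adjusted p = 0.0551) and 8 metallothioneins (0.642; MT1F 1.36 ± 0.37). The same held for 5 iron handling genes (0.204; CYBRD1, an iron reductase, 0.53 ± 0.13), 10 heat shock genes (0.253; CHORDC1 -0.63 ± 0.23), 16 cholesterol synthesis genes (0.208; FDPS -0.83 ± 0.22, another probe set -0.37) and 11 oxidative phosphorylation genes (0.967, or 0.194 without HCI-2509 replicate 1; UQCRC1 0.60 ± 0.19, with a median of -0.0031, or 0.14 without that array, a mean of 0.02 and a test direction of higher). Adjusted over the list alone, 1 endoplasmic reticulum member was lower and 2 iron handling members were higher, and 0 members of the other 5 lists passed. At an unadjusted p under 0.05 the members higher and lower were 2 and 0 of p53 targets, 1 and 2 of endoplasmic reticulum genes, 1 and 0 of metallothioneins, 2 and 0 of iron handling, 0 and 2 of heat shock, 1 and 3 of cholesterol synthesis and 1 and 0 of oxidative phosphorylation genes. CDKN2A, the 1 measured gene of the CDK inhibitor list, was -0.10 ± 0.15, or -0.05 without HCI-2509 replicate 1. Leaving out that array also gave 2 lower endoplasmic reticulum members, XBP1 at -0.74 (adjusted p = 0.0207) and SDF2L1, a chaperone partner, at -0.64 (adjusted p = 0.0198), and 1 lower p53 target, GDF15, a stress-induced cytokine, at -0.55 (adjusted p = 0.0435). In that fit BBC3 was 0.33 and CHORDC1 -0.39, and neither passed.

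Markers of other cell types gave 1 call. Of 7 measured endothelial markers PECAM1 fell (camera adjusted p = 0.721; median 0.23, or 0.14 without HCI-2509 replicate 1, and mean -0.03), and adjusted over the list alone 2 rose and 1 fell. Of 3 fibroblast markers and 4 leukocyte markers, given as values only, 0 passed in limma, also adjusted over each list alone or at an unadjusted p under 0.05. Their largest changes were 0.17 ± 0.12 for DCN, the matrix proteoglycan decorin, and 0.50 ± 0.23 for CD53, a leukocyte tetraspanin.

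Of the 59 named genes that passed, 37 also passed in each of the 6 fits that left out 1 array. The others were KDM1A, GPX8, CCNE2, KIF14, HMMR, CTH, GSR, BNIP3, ATG16L1, CTSB, ST14, OVOL1, CLDN4, LAMP3, ETV5, DUSP6, EPHA4, EGF, FGFR1, B2M, IL11 and WDR12, each of which kept its direction.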

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

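Of the tests in this part, those of HCI-2509 replicate 1 and of the mitosis list were chosen only after the result was seen, and the count of splits was planned.

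Signal that changed was also present in probe sets the comparisons of genes do not use. Of 37519 probe sets without a gene name here, 147 passed limma's adjusted p of 0.05 when tested on their own (0.392%; 4266 had an unadjusted p under 0.05). Of these, 73 were higher with HCI-2509, each with all 3 treated arrays above all 3 untreated arrays, and 74 were lower. The largest changes among probe sets without a gene name were 5.16 and -3.26, and the median signal of all such probe sets was 4.08, against 5.34 for the genes tested.

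HCI-2509 replicate 1 lay apart from the other arrays. Among genes called without it, rises on it were 0.683 of those on the other treated arrays, and falls were 1.36, as medians. The 95% intervals over genes, taken as independent, were 0.627 to 0.746 and 1.27 to 1.43. Ratios taken in the same way for HCI-2509 replicates 2 and 3 were 0.995 and 0.949 for rises and 0.781 and 0.794 for falls. The genes were called with the arrays that a ratio is set against, so its reference need not be 1. The ratios of HCI-2509 replicate 1 point opposite ways and were taken on values not corrected for signal level. They therefore cannot tell whether the response was stronger there. A dependence on signal level is present, with a median deviation of 0.095 in the dimmest 2977 genes and -0.30 in the brightest 2977, but cyclic loess normalization lowered the SD of its deviations only from 0.499 to 0.463, against at most 0.318 on the other arrays, so level is unlikely to be the whole cause. An array of untreated cells is argued against by the 93.4% of genes called without it that lay on the side of the other treated arrays. RNA quality, labelling and the state of that culture stay open and were not tested.

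The mitosis list was lower, with a median of -0.67 (interval over genes, taken as independent, -0.88 to -0.57), a call lost with an estimated correlation (adjusted p = 0.207), and the DNA replication list did not pass. The array that lay apart does not account for this, since the median without it was -0.557, and neither does signal level, since the middle 95% of 10000 random lists matched on level began at -0.233. A smaller share of dividing cells that lowers genes of both phases alike is argued against only weakly by the median of the replication list, 0.0678 (interval over genes -0.16 to 0.22), as that interval too takes genes as independent. As a hypothesis found and tested on the same data, the compound may lower mitotic transcripts beyond what a uniform loss of dividing cells gives. A shift between phases of the cycle stays open and was not tested.

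With 6 arrays there are 10 ways to form groups of 3 and 3, too few for a share under 0.05. The real groups gave 766 genes, 1 of the 10 splits gave as many, the real one included, and the highest of the other splits gave 0. Every other split mixes treated and untreated arrays within each group. A real difference then adds to the spread within groups and lowers the count, so the 0 does not measure chance alone.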

How the results depend on the processing

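All alternatives were planned except the test of all probe sets together, which was chosen after the result was seen. None of the 59 named genes that passed changed direction under any alternative, nor did the 6 lists that passed, and in the fits with other scaling, filters, moderation, weights, probe sets, block or arrays 0 calls were opposite to those among the 766. Quantile normalization, median centring, cyclic loess, the filter on dim genes, the intensity trend and the 2 other ways of treating several probe sets gave 702 to 989 genes, within 1.5 times of 766, though quantile normalization put more genes higher (446) than lower (409) and median centring gave 286 higher and 416 lower. For the total, the genes that rose, the genes that fell and those changed at least 2-fold, the values were 196, 103, 93 and 85 without variance moderation, 254, 128, 126 and 224 with treat, and 260, 131, 129 and 208 with all probe sets together, where more tests are adjusted for. Array weights gave 1566 genes (786 higher, 780 lower), and an unadjusted p with a 2-fold change gave 453 (185 higher, 268 lower). The replicate block gave 497 genes (220 higher, 277 lower), with 51 of the 59 named genes passing (not KDM1A, adjusted p = 0.104, nor ATG16L1, CTSB, CLDN4, LAMP3, EGF, B2M and WDR12). No pairing of the arrays by replicate number was seen. Arrays of the same number correlated in their deviations at -0.0157, -0.0178 and -0.0258, and no array correlated best with the array of its own number. The block changed the call of 0 lists. Whether arrays of the same number were handled together is not given by the labels, and these values cannot show it. Leaving out 1 array gave 184 to 1217 genes, 95 to 622 higher, 89 to 595 lower and 174 to 327 at least 2-fold, with 184 lowest without untreated replicate 2 and 1217 highest without HCI-2509 replicate 1. Each array left out moved the total by more than 1.5 times (194 and 225 without untreated replicates 1 and 3, 419 and 392 without HCI-2509 replicates 2 and 3). The cause of these moves was not tested. Of the 59 named genes, 34 lost their call without variance moderation, and other scaling ended those of KDM1A, ATG16L1, ST14 or B2M. XBP1 and IFIH1 passed after quantile or cyclic loess normalization, with the filter, the trend or array weights, CYBRD1 with the filter or array weights, and MT1F with array weights.

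For lists, an estimated correlation left 0 calls in place of 6 and the rotation test fry, which asks whether a list's own genes move one way, gave 15. The estimated correlation gave adjusted p of 0.207 (mitosis, ATF4 targets and mesenchymal), 0.315 (hypoxia and glycolysis), 0.332 (epithelial) and 0.522 (ribosomal proteins). The correlations themselves were 0.1919 for mitosis, 0.2068 for hypoxia and glycolysis, 0.0569 for epithelial and 0.3822 for ribosomal proteins. For ATF4 targets and mesenchymal genes they were -0.0046 and -0.013, below the preset 0.01. The degrees of freedom also differ between the settings, as stated above, so these losses are not due to gene correlation alone. By fry mitosis, ATF4 targets, hypoxia and mesenchymal genes gave adjusted p of 0.00410 to 0.00511. Ribosomal proteins gave 0.0640 after cyclic loess, 0.0931 with the filter on dim genes, 0.0607 with array weights, 0.204 by fry and 0.00117 to 0.0926 on leaving out 1 array, the last without HCI-2509 replicate 1. The epithelial list gave 0.0655 with array weights, 0.0242 by fry and 0.0264 to 0.109 on leaving out 1 array. Lists that passed only under an alternative were ribosome biogenesis (0.0445 with the intensity trend, 0.0429 with array weights, 0.0262 with single probe sets, 0.00511 by fry, 0.0354 to 0.109 on leaving out 1 array), NRF2 targets (0.0484 with array weights, 0.00511 by fry, 0.0406 to 0.199 on leaving out 1 array) and fatty acid synthesis (0.0429 with array weights, 0.0242 by fry, 0.0257 to 0.337 on leaving out 1 array). By fry alone p53 targets gave 0.0463, iron handling 0.00822, heat shock 0.0242, lysosome and autophagy 0.0174, interferon response 0.00511, NF-kappaB and cytokines 0.0487 and myeloid genes 0.00511. The cause was not tested. With the filter on dim genes 6 of the 27 lists had fewer than 5 members left and gave no value. Camera on a model without variance moderation was not run. Signal near background, as for many of the genes below the median of 5.34, limits what the arrays can resolve.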

Other observations

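The gene lists and tests in this part were all chosen only after the result was seen.

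Genes of intraflagellar transport, which carries cargo along the cilium, were lower with HCI-2509. All 22 measured members were below 0, 11 fell and 0 rose, with a median of -0.77. IFT88 and IFT74, of the complex that moves toward the ciliary tip, fell by 1.33 and 1.17 on the log2 scale, and WDR35, of the complex that returns, fell by 1.12. IFT140 and IFT20 were -0.11 and -0.07 and did not pass. Cytosolic tRNA synthetases, which charge tRNAs with amino acids, were lower too. Of 17 measured members 6 fell and 0 rose, with a median of -0.51, or -0.47 without HCI-2509 replicate 1. MARS1, for methionine, fell by 1.19, SARS1, for serine, by 0.89, and IARS1, for isoleucine, by 0.86, while KARS1, for lysine, was 0.19 and did not pass. Both lists were kept from 6 groups of genes looked over after the passing genes were seen. The transport list came from a wider group of cilium genes. Members were thus seen before the lists were chosen, so no camera test of either list is given. None of the measured members of these lists is in a list fixed beforehand (0 of 22 and 0 of 17). Whether they share regulation with a fixed list, such as the ATF4 targets, was not tested. The medians stayed below 0 under quantile, median and cyclic loess scaling.

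Genes of the cornified envelope, the protein shell of cells in the outer layer of squamous epithelium, moved both ways. Of 43 measured members 7 rose and 2 fell, with a median of 0.23, or 0.24 without HCI-2509 replicate 1. Beside SPRR1B and SPRR1A, LCE3D rose by 2.27, A2ML1, a protease inhibitor, by 2.01, SPRR2A by 1.71, KLK5, a kallikrein protease, by 1.66 and SLPI, a secreted protease inhibitor, by 1.62. Without HCI-2509 replicate 1 the rise of LCE3D was 2.85. TGM5, a transglutaminase, changed by -1.04 and KLK7, another kallikrein, by -0.64. The list was assembled after SPRR1B, SPRR1A and other passing members were seen, so no test of it is given. The SPRR and LCE genes are also similar in sequence, so their signals may not be independent, which was not tested.

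The fall of intraflagellar transport genes was weighed against 2 technical explanations. Without HCI-2509 replicate 1 the median was -0.629 and 13 members fell, so that array is unlikely to be the source. The list was chosen because members fell, so its rank among random lists is not used, but other genes matched to it on signal level had a median of -0.0148, which argues against a fall of genes of that level as a class. An effect of the compound on ciliary transcripts may account for it, as a hypothesis from the same data. Cilia were not measured, and whether the genes fell with the cell cycle was not tested.

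By kind of gene, 713 of 11916 protein-coding genes passed (5.98%), 29 of 1398 long non-coding RNAs (2.07%) and 12 of 1072 microRNA genes (1.12%).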
